A study of Mus musculus with 24 samples.

How the data were processed

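RNA sequencing of whole liver was deposited for 24 male C57BL/6 mice in 4 groups of 6, made as 2 cohorts of 3 mice per group. Mice were injected intraperitoneally at 20 to 21 weeks with an adeno-associated virus carrying Cre recombinase and were killed 4 weeks later, on chow and after a 4 h fast. Libraries were stranded and poly(A)-selected. The labels name Salmon, DESeq2 and the genome GRCm38.p6 without tool versions or settings.

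The deposited table holds, in the unit signal, estimated counts per gene that the authors divided by a size factor per library. This reading rests on the values. The median over genes of the log ratio to the mean of all libraries was the same in the 24 columns, and 60.6 to 66.0% of the low values were within 0.02 of whole multiples of a step of 0.686 to 1.46 normalized counts, so that whole reads could not be recovered. Library totals were 23385900 to 27190700 normalized counts, which the steps turn into an estimated 18640900 to 34286900 reads. Of 54432 gene identifiers, 54050 (99.3%) were found with their version in GENCODE M21, which gave symbols and coordinates. Columns name the group, a letter and a number but not the mouse, so the labels do not assign cohorts to columns. Taken by number and then by letter, the groups of the columns run in the order of the sample titles. If columns follow that order, number 1 lies in the first cohort and number 3 in the second. The labels do not state this order, and no cohort term was fitted.

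Values were analysed with limma 3.58.1 in R 4.3.3 with an intensity trend, on log2 of the value plus 1, for the 19810 genes with a mean of at least 1. A single model with the 4 group means as coefficients held all 24 libraries, and 6 comparisons were read from it, namely the libraries labelled Trib1-KO, Cebpa-KO and DKO against WT, DKO against Cebpa-KO, DKO against the libraries labelled Trib1-KO, and the interaction, which is the difference between DKO and Cebpa-KO minus that between the libraries labelled Trib1-KO and WT. Genes with a limma adjusted p (Benjamini-Hochberg over the genes tested) under 0.05 were called. The plan for count data could not be used because the values are not counts, and its written alternative for other values was used in its place. Comparisons, gene lists and the rule for naming genes were written before the data were examined.

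Of 39 fixed gene lists, 37 with at least 5 measured members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Camera adjusted p values come from limma and were adjusted over the lists tested. The lists were apolipoproteins and lipoprotein assembly, cholesterol synthesis, fatty acid and triglyceride synthesis, fatty acid oxidation and ketogenesis, lipid droplet and fatty acid uptake, bile acid synthesis and transport, gluconeogenesis and glycogen, urea cycle and amino acid catabolism, C/EBP and Tribbles families and the COP1 ligase, hepatocyte transcription factors, acute phase proteins, complement and coagulation, secreted plasma carriers, xenobiotic metabolism, NRF2 antioxidant genes, male-biased liver genes, female-biased liver genes, pericentral hepatocytes, periportal hepatocytes, fetal liver genes, cell cycle, unfolded protein response, interferon-stimulated genes, extracellular matrix and fibrosis, oxidative phosphorylation, ribosomal proteins, mitochondrially encoded transcripts, immediate early genes, circadian clock, Kupffer cell and macrophage markers, sinusoidal endothelial markers, hepatic stellate cell markers, cholangiocyte markers, lymphocyte markers, neutrophil markers, erythroid markers, pancreatic acinar markers and adipocyte and muscle markers. Counts adjusted over the list alone use the members' own p values. For a list, measured members are those tested in the fit. Marker scores are means of log2 values over the members of a marker list, and family sums add the values of related genes before the log.

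Trib1, Cebpa, Apob and Sort1 were always named. In each comparison, the 6 largest rises and 6 largest falls were named among called genes with a mean value of at least 10. Symbols that are predicted-gene, clone or pseudogene names, such as those of Gm and a number, were left out. Every library of the group named first had to lie on the same side of the other group's mean, without this last condition for the interaction. Fewer were named where fewer met the rule. Up to 4 members with the smallest adjusted p were taken from each list described, and called members of the C/EBP list and of 1 list that, like some genes, is not reported here. Members used again to compare the same gene across groups, and the imprinted genes beside Meg3, were chosen after their values were seen.

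Single values were compared with exact permutation tests over all 924 arrangements of 6 against 6 libraries, whose smallest 2-sided p is 0.00216. Overlaps of calls were set against independent lists. For comparisons that share WT libraries, 100 simulations without effects and a split of the WT libraries by column letter gave the part due to sharing. Group labels were redrawn 100 times per comparison, the real labels included. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.

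Between libraries of the same group, the SD over genes of the log2 difference was 0.393 to 0.597 in 60 pairs, over 10129 genes with a mean above 100. Tested on simulated data, the fit for the libraries labelled Trib1-KO against WT recovered 51% of 100 genes changed 1.5-fold and 68% of 100 changed 2-fold among 19810 genes, and 10 of its 129 calls were unchanged genes. The changed genes were drawn only from genes with a mean log2 value above that of 10 normalized counts. The shares recovered therefore do not cover genes with lower values. In simulated Cebpa-KO data camera recovered 2 of 2 changed lists with either correlation and called 1 other list with the preset one. Genes were drawn independently there, so the simulation cannot show how camera behaves with correlated members. In the real data the estimated correlation was 0.70 for acute phase proteins.

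The alternatives tried were pseudocounts of 0.5 and 5, no filter on low values, limma-voom on values divided by the step, only the groups compared in the fit, and each library of the groups compared left out in turn. Added after the values were seen were scaling to library totals, with and without Mup genes, quantile normalization, the column number or letter as a term, and fits without WT B3, Cebpa-KO F3, DKO H2 and DKO H3 or without Cebpa-KO F3 and DKO H1. Raw reads, exons and isoforms were not used here.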

Results

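RNA from whole liver was sequenced in 24 male C57BL/6 mice, with 6 mice in each of 4 groups. The groups were wild type, mice with floxed Trib1, mice with floxed Cebpa and mice with both genes floxed, and all of them received an adeno-associated virus that encodes Cre recombinase, the enzyme that removes a floxed stretch of DNA. Injection was at 20 to 21 weeks of age and the liver was taken 4 weeks later at midday after a 4 h fast. The groups are called WT, Trib1-KO, Cebpa-KO and DKO below, and libraries carry the letter and number of their column. The table held 54432 genes, with 23385900 to 27190700 normalized estimated counts per library and an estimated 18640900 to 34286900 reads behind them. Each library had 19831 to 21189 genes with a value above 0. Log2 fold changes are given with their standard error after ±, and group values as mean ± SD with n = 6.

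The targeted genes were read first. Cebpa, which encodes the transcription factor C/EBPα (ENSMUSG00000034957.10, chromosome 7, 35119293 to 35121928, GRCm38, a gene with a single exon), stood at 6019 ± 1057 normalized counts in WT and at 82.2 ± 17.5 in Cebpa-KO and 82.4 ± 18.1 in DKO, so that the 12 libraries of both groups lay at 50.5 to 102 against 4264 to 7412 in WT. Trib1, which encodes the Tribbles pseudokinase that presents C/EBPα to the COP1 ubiquitin ligase (ENSMUSG00000032501.9, chromosome 15, 59648350 to 59657099, 3 exons), went against its label. It stood at 1224 ± 204 in WT and at 4237 ± 358 in the libraries labelled Trib1-KO, a rise of 1.81 ± 0.24 on the log2 scale that all 6 libraries shared (limma adjusted p = 3.5e-06, exact permutation p = 0.00216, the smallest that 6 against 6 libraries can give). In Cebpa-KO it stood at 333 ± 158 and in DKO at 732 ± 259. The table holds 1 value per gene, so it cannot show whether the deleted part of Trib1 was lost, and these groups are written below as the libraries labelled Trib1-KO and DKO. Tests are 2-sided unless given as 1-sided.

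**Figure D1:**
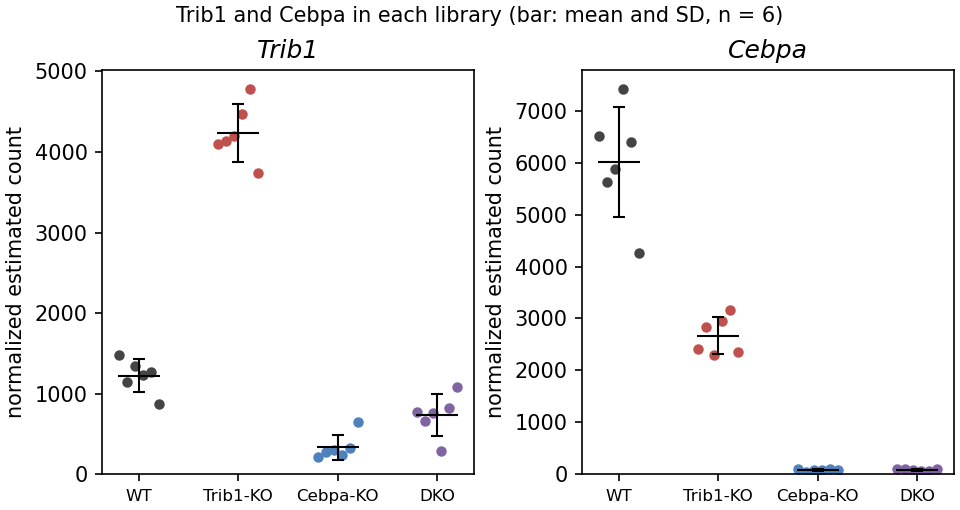
Normalized estimated counts of Trib1 and Cebpa in each of the 24 libraries by group, with the mean and SD of 6 libraries as bars. Trib1 lay at 3734 to 4784 in the libraries labelled Trib1-KO against 874 to 1475 in WT, and Cebpa at 58.1 to 102 in DKO.

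Apob, the structural protein of LDL (chromosome 12, 7977648 to 8016835), was -0.21 ± 0.07 in the libraries labelled Trib1-KO (adjusted p = 0.034), a direction that turned with values scaled to library totals without the major urinary protein (Mup) genes, called the Mup-free scaling below (0.033, adjusted p = 0.77, in a range from 7.6e-04 to 0.77 over 12 alternatives). It was -0.06 and 0.09 in Cebpa-KO and DKO without passing, but 0.15 and 0.31 with quantile normalization, of which the second passed (adjusted p = 0.022). Sort1, the sorting receptor sortilin (chromosome 3, 108284082 to 108361511), was lower in Cebpa-KO at -0.58 ± 0.13 (adjusted p = 0.0038). It stood at 0.23 ± 0.13 in the libraries labelled Trib1-KO and -0.10 ± 0.13 in DKO, neither of which passed. With the Mup-free scaling the first was 0.47 and passed (adjusted p = 0.012, in a range from 0.012 to 0.40 over 12 alternatives).

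The libraries labelled Trib1-KO were compared with WT, with Cebpa not floxed in either. Of female-biased liver genes 9 of 20 rose, by up to 9.96 on the log2 scale. Serum albumin and 20 of 28 complement and coagulation genes fell, and many macrophage, interferon and cell cycle genes rose, but of these lists only the female-biased one held with an estimated correlation. Of 19810 genes tested, 2330 rose and 2168 fell, of which 1138 and 553 by at least 2-fold. The largest rises shared by all 6 libraries were Cyp2b9 at 9.96 ± 0.78, a cytochrome P450 of female mouse liver, Sult3a1 at 8.92 ± 0.33, a sulfotransferase, and Mup18 at 8.61 ± 0.99 and Mup8 at 8.15 ± 0.66, major urinary proteins. Next came Gldn at 7.97 ± 0.46, which encodes gliomedin, and Moxd1 at 7.29 ± 0.96, a monooxygenase. The largest falls were Selenbp2 at -7.71 ± 0.33, a selenium-binding protein, Clec2h at -7.50 ± 0.30, a C-type lectin, and Adgrf1 at -5.60 ± 0.36, an adhesion receptor. Enho, which encodes adropin, stood at -5.31 ± 0.31, Ugt2b38 at -5.07 ± 0.71, a glucuronosyltransferase, and Dsg1c at -4.60 ± 0.33, a desmoglein. All 12 had an adjusted p of 6.3e-06 or less.

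Among female-biased liver genes, 9 of 20 measured members rose, 0 fell and 11 did not pass the test (10 and 1 adjusted over the list alone, camera adjusted p = 4.8e-06, and adjusted p = 0.023 with an estimated correlation). They included Cyp2b13, listed at 0 in all WT libraries and at 154 ± 91.0 in those labelled Trib1-KO, the estrogen sulfotransferase gene Sult1e1 at 6.83 ± 0.47 and Cyp17a1 at 4.35 ± 0.31. Of male-biased liver genes, 0 of 18 measured members rose, 8 fell and 10 did not pass the test (2 and 10 adjusted over the list alone, camera adjusted p = 3.4e-05, and adjusted p = 0.26 with an estimated correlation). The pheromone gene Mup20 stood at -3.17 ± 0.22, Cyp2d9 at -1.08 ± 0.09 and the oxysterol hydroxylase gene Cyp7b1 at -1.91 ± 0.26. Not all members were lower. Mup7 stood at 902974 ± 103211 normalized counts against 292251 ± 151568 in WT, where B3 lay at 30280, and did not pass. For xenobiotic metabolism, 4 of 24 measured members rose, 15 fell and 5 did not pass the test (5 and 15 adjusted over the list alone, camera adjusted p = 6.5e-10, and adjusted p = 0.023 with an estimated correlation). Cyp2c29 stood at -3.96 ± 0.11, Cyp2c37 at -4.51 ± 0.21 and Cyp2c54 at -4.06 ± 0.19. Reads of near-identical family members can be split wrongly, so single members of the Mup, Cyp2c, Cyp2b, Cyp3a, Sult and Serpina1 families are uncertain and their sums were also compared. The Mup sum rose by 1.91 ± 0.27 and took 24.0% of all values against 7.02% in WT. Cyp2b and Sult3a sums rose by 3.63 ± 0.44 and 8.97 ± 0.39. The Cyp2c, Cyp3a, Sult2a and Serpina1 sums were -2.11 ± 0.09, -0.79 ± 0.11, -0.56 ± 0.14 and -0.49 ± 0.07, with exact permutation p after adjustment over 35 sums of 0.0120 or less.

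Genes for proteins that hepatocytes secrete into plasma were often lower. Of complement and coagulation genes, 1 of 28 measured members rose, 20 fell and 7 did not pass the test (1 and 21 adjusted over the list alone, camera adjusted p = 7.5e-14, and adjusted p = 0.15 with an estimated correlation). Examples were the prekallikrein gene Klkb1 at -1.15 ± 0.07, the protein C gene Proc at -0.89 ± 0.06 and C8a, a subunit of the membrane attack complex, at -1.96 ± 0.14. Among secreted plasma carriers, 1 of 18 measured members rose, 12 fell and 5 did not pass the test (2 and 13 adjusted over the list alone, camera adjusted p = 6.2e-07, and adjusted p = 0.097 with an estimated correlation), where Alb, serum albumin, was -2.02 ± 0.15 and took 1.39% of all values against 5.82% in WT, the selenium carrier Selenop was -0.79 ± 0.08 and A1bg was 3.03 ± 0.43. Acute phase proteins went both ways, since 6 of 24 measured members rose, 5 fell and 13 did not pass the test (7 and 6 adjusted over the list alone, camera adjusted p = 0.65). The orosomucoid gene Orm3 stood at 5.72 ± 0.77 and Apcs, serum amyloid P, at 2.48 ± 0.44 against the fibrinogen gene Fga at -1.11 ± 0.23. Markers of macrophages rose in the same libraries by a mean of 0.71 ± 0.14 (exact permutation p = 0.00649).

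No list of lipid metabolism held with an estimated correlation. Fry, which does not set a list against the other genes, called all the lists counted in this paragraph (fry adjusted p from 1.8e-06 to 0.024). For cholesterol synthesis, 0 of 22 measured members rose, 14 fell and 8 did not pass the test (0 and 16 adjusted over the list alone, camera adjusted p = 1.7e-09, and adjusted p = 0.17 with an estimated correlation). Ebp stood at -1.01 ± 0.06 and Tm7sf2 at -1.44 ± 0.10, both enzymes of the late pathway. The lipoprotein receptor gene Vldlr was 3.91 ± 0.36, and the annexin gene Anxa2 2.63 ± 0.10. The SREBP regulators Insig2, Insig1 and Scap stood at 1.40 ± 0.16, -0.85 ± 0.11 and -0.68 ± 0.10, Lrp1 -0.51 ± 0.12 and the ubiquitin ligase gene Mylip 0.40 ± 0.11. Of apolipoproteins and lipoprotein assembly genes, 5 of 21 measured members rose, 11 fell and 5 did not pass the test (5 and 11 adjusted over the list alone, camera adjusted p = 0.0071, and adjusted p = 0.17 with an estimated correlation). Apoa1 stood at -1.32 ± 0.09 and Lipc, hepatic lipase, at -0.99 ± 0.08 against Apoa4 at 4.55 ± 0.32. The list median of -0.21 turned to 0.03 with the Mup-free scaling. For fatty acid and triglyceride synthesis, 9 of 22 measured members rose, 3 fell and 10 did not pass the test (9 and 3 adjusted over the list alone, camera adjusted p = 0.020, and adjusted p = 0.43 with an estimated correlation). Pnpla3 stood at 5.55 ± 0.77 and Elovl6 at 1.15 ± 0.18. In lipid droplet and fatty acid uptake, 8 of 19 measured members rose, 3 fell and 8 did not pass the test (9 and 3 adjusted over the list alone, camera adjusted p = 0.013, and adjusted p = 0.31 with an estimated correlation). Cidec stood at 3.67 ± 0.47, a droplet-fusion protein, and Fabp4 at 1.95 ± 0.19. For fatty acid oxidation and ketogenesis, 3 of 22 measured members rose, 11 fell and 8 did not pass the test (3 and 11 adjusted over the list alone, camera adjusted p = 0.0082, and adjusted p = 0.52 with an estimated correlation). Cyp4a10 stood at -3.29 ± 0.36. The list median of -0.24 turned to 0.0038 with the Mup-free scaling. Of bile acid synthesis and transport genes, 3 of 18 measured members rose, 6 fell and 9 did not pass the test (3 and 6 adjusted over the list alone, camera adjusted p = 0.13).

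In the list of C/EBP and Tribbles families and the COP1 ligase, 6 of 13 measured members rose, 3 fell and 4 did not pass the test (7 and 3 adjusted over the list alone, camera adjusted p = 0.31). Cebpa itself was -1.16 ± 0.16 (adjusted p = 5.3e-06), Cebpe -1.69 ± 0.13 and Cebpz -0.30 ± 0.10, while Ddit3 (the stress factor CHOP), Trib3, Cebpg, Det1 and Ddb1 stood at 1.15, 0.64, 0.45, 0.42 and 0.23. Hepatocyte transcription factors numbered 3 up and 6 down of 18 (3 and 7 adjusted over the list alone), camera adjusted p = 0.030, and adjusted p = 0.17 with an estimated correlation. The nuclear receptor gene Nr1i3 stood at -1.39 ± 0.15. The list median of -0.21 turned to 0.04 with the Mup-free scaling. Genes of the urea cycle and amino acid catabolism numbered 1 up and 10 down of 22 (1 and 11 adjusted over the list alone), camera adjusted p = 3.6e-04, and adjusted p = 0.38 with an estimated correlation. Otc stood at -1.23 ± 0.08 and Ass1 at -1.16 ± 0.14. NRF2 antioxidant genes numbered 9 up and 3 down of 15 (9 and 3 adjusted over the list alone), camera adjusted p = 1.5e-04, and adjusted p = 0.17 with an estimated correlation. Srxn1 stood at 1.76 ± 0.18 and Gclm at -0.70 ± 0.07. Oxidative phosphorylation numbered 0 up and 14 down of 22 (0 and 18 adjusted over the list alone), camera adjusted p = 9.2e-08, and adjusted p = 0.26 with an estimated correlation, a median of -0.23 that turned to 0.01 with the Mup-free scaling, with 0 members then passing in each direction. Periportal hepatocytes' genes numbered 1 up and 6 down of 15 (1 and 6 adjusted over the list alone), camera adjusted p = 0.0098, and adjusted p = 0.38 with an estimated correlation. Cyp2f2 stood at -1.23 ± 0.10. The list median of -0.17 turned to 0.07 with that scaling and 0.02 with quantile normalization.

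Several lists did not pass as a whole in the libraries labelled Trib1-KO. Pericentral hepatocyte genes numbered 3 up and 6 down of 15 (3 and 6 adjusted over the list alone, camera adjusted p = 0.23). Cyp2e1 stood at -1.26 ± 0.11 and the cation transporter gene Slc22a3 at 2.62 ± 0.27. Gluconeogenesis and glycogen genes numbered 5 up and 2 down of 16 (5 and 3 adjusted over the list alone, camera adjusted p = 0.34), and circadian clock genes 1 up and 3 down of 16 (1 and 3 adjusted over the list alone, camera adjusted p = 0.31). The unfolded protein response numbered 4 up and 0 down of 18 (4 and 0 adjusted over the list alone, camera adjusted p = 0.51). In it the asparagine synthetase gene Asns was 2.23 ± 0.47 and the median (-0.02) and mean (0.19) differed in sign. Fetal liver genes numbered 1 up and 1 down of 12 (1 and 1 adjusted over the list alone, camera adjusted p = 0.55), among them Ly6d at 6.35 ± 0.41. Ribosomal proteins numbered 1 up and 0 down of 26 (0 and 0 adjusted over the list alone, camera adjusted p = 0.31) and mitochondrially encoded transcripts 0 up and 1 down of 13 (0 and 1 adjusted over the list alone, camera adjusted p = 0.31). Pancreatic acinar markers and adipocyte and muscle markers had 2 and 3 measured members and got no list test, and of these Cela1 was -0.70 ± 0.17 and the resistin gene Retn 2.67 ± 0.33.

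Many interferon, macrophage, cell cycle and matrix genes rose in the libraries labelled Trib1-KO, in lists that did not hold with an estimated correlation. Of interferon-stimulated genes, 14 of 18 measured members rose, 0 fell and 4 did not pass the test (14 and 0 adjusted over the list alone, camera adjusted p = 1.5e-07, and adjusted p = 0.19 with an estimated correlation). The GTPase gene Gbp3 stood at 2.06 ± 0.26 and Oas1a at 1.36 ± 0.20. Of Kupffer cell and macrophage markers, 10 of 12 measured members rose, 0 fell and 2 did not pass the test (10 and 0 adjusted over the list alone, camera adjusted p = 1.5e-07, and adjusted p = 0.17 with an estimated correlation). Cd68 stood at 1.37 ± 0.20 and Cd5l at 1.00 ± 0.15. Cell cycle genes numbered 15 up and 1 down of 25 (15 and 1 adjusted over the list alone), camera adjusted p = 5.2e-06, and adjusted p = 0.17 with an estimated correlation. The proliferation marker Mki67 stood at 1.80 ± 0.28 and E2f1 at -0.73 ± 0.12. Extracellular matrix and fibrosis genes numbered 9 up and 0 down of 16 (11 and 0 adjusted over the list alone), camera adjusted p = 2.3e-05, and adjusted p = 0.17 with an estimated correlation. Timp1 stood at 2.97 ± 0.62 and Col3a1 at 1.09 ± 0.20. Immediate early genes numbered 6 up and 0 down of 12 (8 and 1 adjusted over the list alone), camera adjusted p = 0.0014, and adjusted p = 0.26 with an estimated correlation. The stress factor gene Atf3 stood at 5.46 ± 0.39. Among markers of other cells, cholangiocyte markers numbered 0 up and 4 down of 12 (0 and 4 adjusted over the list alone), camera adjusted p = 0.022, and adjusted p = 0.17 with an estimated correlation. Neutrophil markers numbered 3 up and 0 down of 8 (3 and 0 adjusted over the list alone), camera adjusted p = 0.027, and adjusted p = 0.38 with an estimated correlation. Sinusoidal endothelial markers numbered 3 up and 2 down of 12 (3 and 3 adjusted over the list alone, camera adjusted p = 0.64) and hepatic stellate cell markers 3 up and 0 down of 12 (3 and 0 adjusted over the list alone, camera adjusted p = 0.18). Lymphocyte markers numbered 3 up and 1 down of 12 (3 and 1 adjusted over the list alone, camera adjusted p = 0.41) and erythroid markers 0 up and 0 down of 6 (0 and 0 adjusted over the list alone, camera adjusted p = 0.45). The mean over 12 macrophage markers exceeded that over 12 endothelial markers by 0.63 ± 0.14 (exact permutation p = 0.00433, 0.0216 after adjustment over 35 tests).

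Camera with a preset correlation called 22 of 37 lists, 10 up and 12 down, and 2 of them, xenobiotic metabolism and female-biased liver genes, held with an estimated correlation. The deposited scale makes the median log ratio equal in all libraries, and the median of all genes was 0.0077 in this comparison. Scaling to library totals without Mup genes put this median at 0.24. It put the median at -0.28 in DKO against the libraries labelled Trib1-KO and at -0.23 in the interaction. With that scaling the share of calls that rose in this comparison went from 51.8% to 83.9%. The direction of some changes therefore depends on the scaling chosen.

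**Figure D2:**
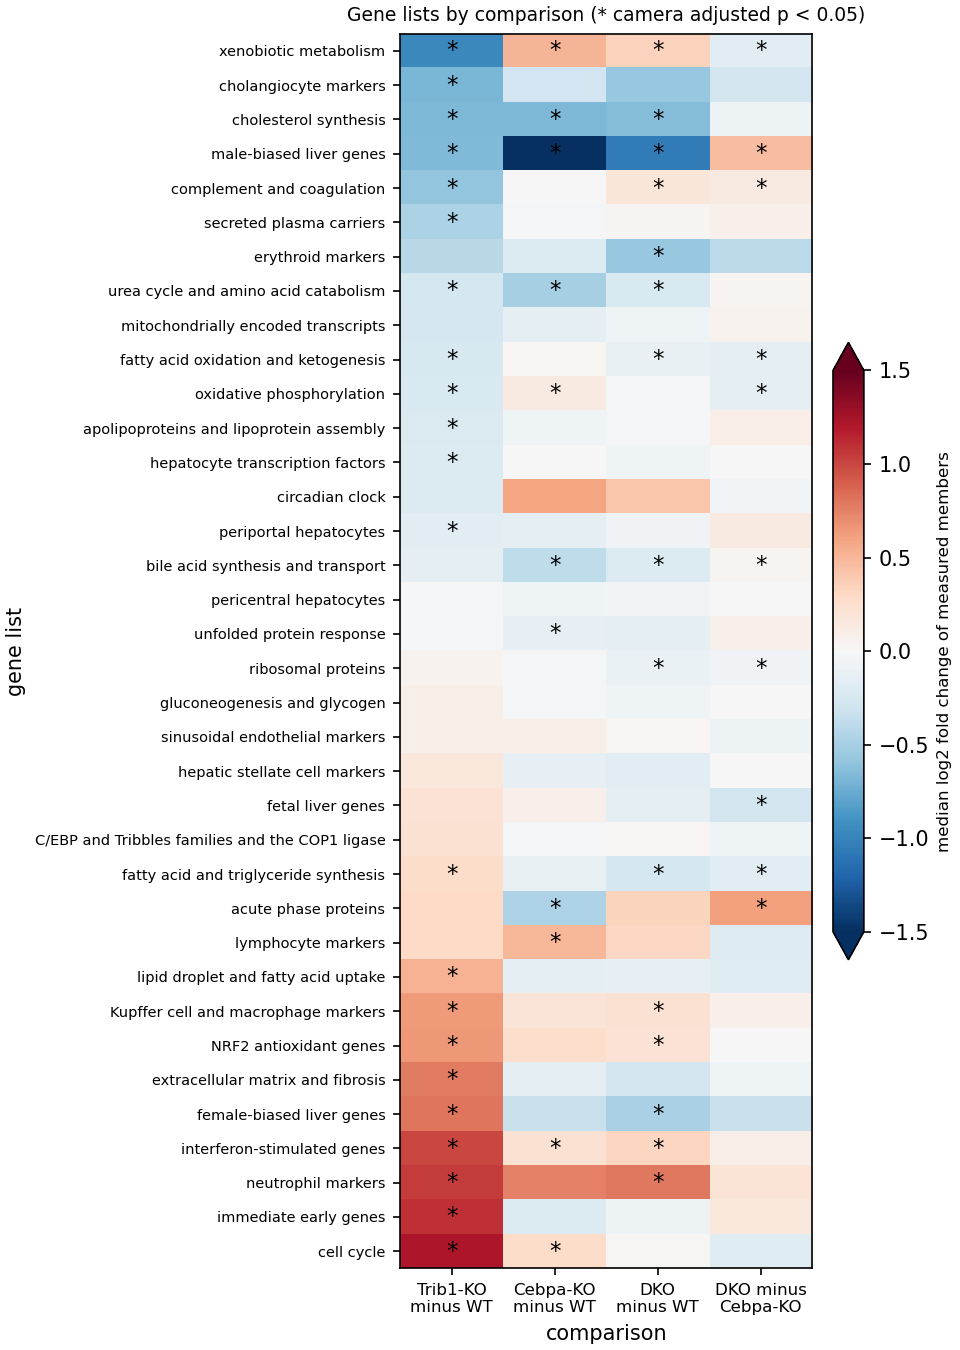
Median log2 fold change of the measured members of the gene lists shown in 4 comparisons, with an asterisk where camera with a preset correlation passed. Xenobiotic metabolism had a median of -0.96 in the libraries labelled Trib1-KO and 0.51 in Cebpa-KO, while cholesterol synthesis stood at -0.67, -0.67 and -0.65 in the first 3 comparisons.

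Cebpa-KO against WT asks what C/EBPα does in the adult liver. Many genes for cholesterol synthesis, bile acid handling, the urea cycle and the male liver program fell and 12 of 24 xenobiotic genes rose, but of these lists only bile acids held with an estimated correlation. The imprinted transcripts Rian and Meg3 were among the largest rises. In total 912 genes rose and 1034 fell, 250 and 376 of them by at least 2-fold. The largest rises in all 6 libraries were Rian at 4.50 ± 0.26 and Meg3 at 4.24 ± 0.22, maternally expressed long noncoding RNAs. Adam32 stood at 4.04 ± 0.46, Mas1, a receptor of the renin-angiotensin system, at 3.91 ± 0.59, Lrtm2 at 3.78 ± 0.82 and the glutathione peroxidase gene Gpx6 at 3.51 ± 0.39. Cebpa, the floxed gene, was -6.19 (adjusted p = 6.8e-19). The other largest falls that met the same rule were Mup19 at -10.01 ± 1.31, Mup15 at -8.95 ± 1.76, Mup7 at -8.48 ± 0.81, Mup17 at -5.67 ± 0.97 and the orosomucoid gene Orm1 at -6.99 ± 1.18. The 11 genes other than Cebpa had an adjusted p of 0.0029 or less. The Mup sum was -1.98 ± 0.29 and took 1.75% of all values, and the Serpina1 sum was -1.11 ± 0.10 (exact permutation p after adjustment of 0.00446).

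For cholesterol synthesis, 0 of 22 measured members rose, 12 fell and 10 did not pass the test in Cebpa-KO (0 and 15 adjusted over the list alone, camera adjusted p = 1.3e-09, and adjusted p = 0.28 with an estimated correlation). The squalene epoxidase gene Sqle stood at -2.15 ± 0.31 and Msmo1 at -1.16 ± 0.19. Insig2 stood at -2.09 ± 0.16 and Srebf2, the transcription factor SREBP-2, at -0.73 ± 0.15. Of bile acid synthesis and transport genes, 1 of 18 measured members rose, 10 fell and 7 did not pass the test (3 and 11 adjusted over the list alone, camera adjusted p = 1.1e-05, and adjusted p = 0.034 with an estimated correlation). The bile acid uptake transporter gene Slc10a1 stood at -0.98 ± 0.08 and the sterol 12-hydroxylase gene Cyp8b1 at -1.20 ± 0.20. Male-biased liver genes numbered 1 up and 9 down of 18 (2 and 11 adjusted over the list alone), camera adjusted p = 2.0e-12, and adjusted p = 0.12 with an estimated correlation. Susd4 stood at -3.64 ± 0.25 and Elovl3 at -2.20 ± 0.22. In the female-biased list 0 rose and 4 fell of 20 (3 and 4 adjusted over the list alone, camera adjusted p = 0.13), among them Cyp17a1 at -2.28 ± 0.31. Genes of the urea cycle and amino acid catabolism numbered 1 up and 12 down of 22 (2 and 14 adjusted over the list alone), camera adjusted p = 1.1e-05, and adjusted p = 0.51 with an estimated correlation. Got1 stood at -1.77 ± 0.32 and Otc at 0.51 ± 0.08. For xenobiotic metabolism, 12 of 24 measured members rose, 4 fell and 8 did not pass the test (13 and 6 adjusted over the list alone, camera adjusted p = 9.6e-04, and adjusted p = 0.28 with an estimated correlation). Cyp2c55 stood at 2.59 ± 0.21 and the glutathione transferase gene Gstm3 at 2.03 ± 0.26.

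Oxidative phosphorylation numbered 4 up and 0 down of 22 (5 and 0 adjusted over the list alone) in Cebpa-KO, camera adjusted p = 5.3e-05, and adjusted p = 0.59 with an estimated correlation. Acute phase proteins numbered 1 up and 4 down of 24 (1 and 6 adjusted over the list alone), camera adjusted p = 0.0045, and adjusted p = 0.67 with an estimated correlation. Orm3 stood at -3.88 ± 0.77 and Saa4 at -1.37 ± 0.28. Interferon-stimulated genes numbered 2 up and 0 down of 18 (2 and 0 adjusted over the list alone), camera adjusted p = 0.0060, and adjusted p = 0.66 with an estimated correlation. Cell cycle genes numbered 3 up and 0 down of 25 (4 and 0 adjusted over the list alone), camera adjusted p = 0.042, and adjusted p = 0.64 with an estimated correlation. The unfolded protein response numbered 0 up and 2 down of 18 (0 and 2 adjusted over the list alone), camera adjusted p = 0.025, and adjusted p = 0.59 with an estimated correlation. Asns stood at -4.51 ± 0.47. Lymphocyte markers numbered 1 up and 0 down of 12 (1 and 0 adjusted over the list alone), camera adjusted p = 0.032, and adjusted p = 0.35 with an estimated correlation, the member being Ighm, the immunoglobulin M heavy chain, at 1.34 ± 0.26. Of the C/EBP family beside Cebpa, Cebpg and Cebpe stood at 1.48 ± 0.08 and 1.32 ± 0.13, and Trib1 at -1.96 ± 0.24 (adjusted p = 4.1e-06). The lipogenic genes Fasn and Elovl5 were -1.41 ± 0.18 and -1.36 ± 0.22, and lipoprotein lipase Lpl 2.07 ± 0.27. The clotting factor gene F11 was -1.70 ± 0.16 and the fetal gene Spink1 3.73 ± 0.48, all of them in lists that did not pass as a whole. Macrophage, endothelial, stellate and cholangiocyte scores differed from WT by 0.18 ± 0.16, 0.07 ± 0.05, -0.16 ± 0.08 and -0.21 ± 0.13, with exact permutation p of at least 0.0628. Camera called 12 of 37 lists, 5 up and 7 down, of which 2, bile acids among them, held with an estimated correlation. The share of calls that rose was 46.9% against 35.9% with the Mup-free scaling and 58.2% with limma-voom. The lists of fatty acid oxidation, hepatocyte transcription factors and complement had medians of 0.03, 0.01 and 0.01 that differed in sign from their mean or test, none of which passed.

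DKO was compared with WT next. Here 563 genes rose and 643 fell, 146 and 254 of them by at least 2-fold. The largest rises in all 6 libraries were Adam32 at 4.12 ± 0.46, the odorant-binding protein gene Obp2a at 3.97 ± 0.40, Rian at 3.87 ± 0.26, Meg3 at 3.60 ± 0.22, the sphingomyelinase-like gene Smpdl3b at 3.23 ± 0.32 and Lrtm2 at 3.22 ± 0.82. Cebpa was -6.18 (adjusted p = 6.9e-19). The other largest falls were Mup15 at -9.72 ± 1.76, Mup19 at -7.31 ± 1.31, Mup7 at -6.89 ± 0.81, Mup17 at -6.23 ± 0.97 and Mup18 at -5.24 ± 0.99, and the Mup sum was -1.36 ± 0.34 (exact permutation p = 0.00649). For cholesterol synthesis, 0 of 22 measured members rose, 15 fell and 7 did not pass the test (0 and 19 adjusted over the list alone, camera adjusted p = 3.3e-17, and adjusted p = 0.11 with an estimated correlation). Mvd stood at -1.22 ± 0.21 and Fdps at -1.02 ± 0.19. Of fatty acid and triglyceride synthesis genes, 0 of 22 measured members rose, 7 fell and 15 did not pass the test (0 and 8 adjusted over the list alone, camera adjusted p = 1.4e-05, and adjusted p = 0.27 with an estimated correlation), with Fasn, fatty acid synthase, at -1.42 ± 0.18 and the desaturase gene Scd1 at -1.04 ± 0.21. Insig2 stood at -1.79 ± 0.16, Vldlr at -1.66 ± 0.36 and Srebf2 at -0.53 ± 0.15. Bile acid synthesis and transport genes numbered 1 up and 7 down of 18 (3 and 8 adjusted over the list alone), camera adjusted p = 7.6e-04, and adjusted p = 0.11 with an estimated correlation. Slc10a1 stood at -0.70 ± 0.08. Urea cycle and amino acid catabolism genes numbered 0 up and 7 down of 22 (1 and 11 adjusted over the list alone), camera adjusted p = 1.4e-05, and adjusted p = 0.46 with an estimated correlation. Hpd stood at -0.80 ± 0.10.

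In DKO, male-biased liver genes numbered 3 up and 9 down of 18 (3 and 10 adjusted over the list alone, camera adjusted p = 1.7e-08, and adjusted p = 0.23 with an estimated correlation) and female-biased genes 0 up and 4 down of 20 (0 and 4 adjusted over the list alone, camera adjusted p = 0.0012, and adjusted p = 0.11 with an estimated correlation). Susd4 stood at -3.15 ± 0.25 and the peroxisomal transporter gene Abcd2 at -3.65 ± 0.49. Xenobiotic metabolism numbered 8 up and 2 down of 24 (10 and 5 adjusted over the list alone, camera adjusted p = 0.0084, and adjusted p = 0.43 with an estimated correlation). Complement and coagulation numbered 5 up and 2 down of 28 (10 and 2 adjusted over the list alone, camera adjusted p = 0.0013, and adjusted p = 0.52 with an estimated correlation) and fatty acid oxidation and ketogenesis 0 up and 2 down of 22 (0 and 6 adjusted over the list alone, camera adjusted p = 0.011, and adjusted p = 0.60 with an estimated correlation). Interferon-stimulated genes numbered 3 up and 0 down of 18 (6 and 0 adjusted over the list alone, camera adjusted p = 9.4e-05, and adjusted p = 0.46 with an estimated correlation). Ifit1 stood at 1.11 ± 0.25. Kupffer cell and macrophage markers passed as a list with 0 up and 0 down of 12 (0 and 0 adjusted over the list alone, camera adjusted p = 0.0020, and adjusted p = 0.50 with an estimated correlation), beside a score difference of 0.25 ± 0.18 (exact permutation p = 0.186). Ribosomal proteins passed as a list with 0 up and 0 down of 26 (0 and 0 adjusted over the list alone, camera adjusted p = 4.9e-04, and adjusted p = 0.50 with an estimated correlation) and neutrophil markers with 1 up and 0 down of 8 (2 and 0 adjusted over the list alone, camera adjusted p = 0.011, and adjusted p = 0.46 with an estimated correlation). Erythroid markers passed with 0 up and 1 down of 6 (0 and 1 adjusted over the list alone, camera adjusted p = 0.013, and adjusted p = 0.46 with an estimated correlation) and NRF2 antioxidant genes with 2 up and 0 down of 15 (5 and 0 adjusted over the list alone, camera adjusted p = 0.046, and adjusted p = 0.50 with an estimated correlation). Cebpg and Cebpe stood at 1.41 ± 0.08 and 1.39 ± 0.13, and Trib1 at -0.83 ± 0.24 (adjusted p = 0.041). That call was kept in 3 of the 12 fits that left out a library and lost without WT A1, A2, A3, B1 or B2 or DKO G1, G2, G3 or H1, where it lay between -0.86 and -0.58. The cholangiocyte score was -0.49 ± 0.10 (exact permutation p = 0.00216, the smallest possible). With only the WT and DKO libraries in the fit the count was 793, and the share of calls that rose was 46.7% against 36.1% with the Mup-free scaling. The C/EBP, plasma carrier, fetal and immediate early lists, none of which passed, had a median, mean or test that differed in sign.

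Set against WT, the libraries labelled Trib1-KO and those of Cebpa-KO moved many genes in opposite directions. Of 936 genes called in both, 309 rose in the first and fell in the second and 395 did the reverse, against 122 and 99.8 for independent lists, while 93 rose and 139 fell in both, against 107 and 113. Cyp2c29 was -3.96 and 0.72 in the first and second, Cyp17a1 4.35 and -2.28, Otc -1.23 and 0.51 and Rian -3.25 and 4.50. Sqle went the same way in both, at -1.10 ± 0.31 and -2.15 ± 0.31. Both comparisons share the WT libraries, which alone gave a correlation of 0.499 and a covariance of 0.0731 in 100 simulations without effects. The observed correlation across genes, which are not independent replicates, was -0.03 with a covariance of -0.01. With WT libraries A1 to A3 for the first comparison and B1 to B3 for the second it was -0.15 with a covariance of -0.08 and -0.16 with -0.09 the other way round. Cebpa-KO and DKO shared 404 rises and 488 falls, against 25.9 and 33.6 for independent lists, with 0 genes called in opposite directions. Their correlation was 0.72 with a covariance of 0.229, and 0.40 and 0.41 with the WT libraries split, at covariances of 0.156 and 0.159.

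DKO and Cebpa-KO differ by the floxed Trib1 gene, with Cebpa low in both. Here 16 genes rose and 24 fell, against 4498 calls with Cebpa intact. The largest rises shared by all 6 libraries were Acsm2 at 3.27 ± 0.55, an acyl-CoA synthetase, Cldn14 at 3.04 ± 0.52, a claudin, Serpina1e at 2.53 ± 0.50, Cspg5 at 1.58 ± 0.32, Rfx4 at 1.58 ± 0.25 and the glutamine transporter gene Slc1a5 at 1.27 ± 0.27. The largest falls were Cib3 at -2.58 ± 0.52, a calcium-binding protein, the hepcidin gene Hamp2 at -1.72 ± 0.32, Rnf186 at -1.60 ± 0.22, Ighm at -1.58 ± 0.26, Zfp791 at -1.19 ± 0.26 and Scd1 at -1.12 ± 0.21, with adjusted p of at most 0.046 for all 12. Called genes that the rule on symbols leaves out included Mid1-ps1 at 3.81 ± 0.80 and Gm4316 at -2.23 ± 0.24 (adjusted p = 0.043 and 4.8e-05). The Serpina1, Mup and Cyp2b sums differed by 0.45 ± 0.16, 0.62 ± 0.26 and -1.41 ± 0.43 (exact permutation p after adjustment of 0.0448, 0.0494 and 0.0289). Trib1 was 1.13 ± 0.24 (adjusted p = 0.046, exact permutation p = 0.0130), higher than the Cebpa-KO mean in 5 of 6 DKO libraries. It passed without Cebpa-KO F3 or DKO H1 but not without Cebpa-KO E1, E2, E3, F1 or F2 or DKO G1, G2, G3, H2 or H3, where it lay between 1.00 and 1.14. Of the gene lists, acute phase proteins had 0 up and 0 down of 24 (10 and 0 adjusted over the list alone, camera adjusted p = 4.8e-10, and adjusted p = 0.48 with an estimated correlation), where Orm1 stood at 5.23 ± 1.18 (adjusted p = 0.066). Orm1 lay at 39209 and 66375 normalized counts in DKO H2 and H3 against 69.0 to 7769 in the other 4 DKO libraries. Without WT B3, Cebpa-KO F3, DKO H2 and DKO H3 the list median went from 0.62 to 0.30 (camera adjusted p = 1.4e-06). Male-biased genes numbered 2 up and 0 down of 18 (3 and 0 adjusted over the list alone), camera adjusted p = 2.5e-06, and adjusted p = 0.46 with an estimated correlation, namely Serpina1e and Mup3 at 1.20 ± 0.25. Fatty acid and triglyceride synthesis numbered 0 up and 1 down of 22 (0 and 2 adjusted over the list alone), camera adjusted p = 0.0088, and adjusted p = 0.49 with an estimated correlation. Oxidative phosphorylation, complement and coagulation, fatty acid oxidation and ketogenesis, bile acid synthesis and transport, ribosomal proteins, fetal liver genes and xenobiotic metabolism passed as lists with 0 members up and 0 down over all genes, at medians of -0.14, 0.13, -0.14, 0.04, -0.05, -0.28 and -0.17, and adjusted p = 0.42 or more with an estimated correlation. The macrophage score differed by 0.07 ± 0.13 and the cholangiocyte score by -0.28 ± 0.10 (exact permutation p = 0.0173).

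The count of 40 rested on few libraries. It was 23, 24, 26, 23 and 26 without Cebpa-KO E1, E2, E3, F1 and F2, 63 without Cebpa-KO F3, and 18 without DKO G2. It was 79 without both F3 and DKO H1, 18 with only these 2 groups in the fit, 25 without the filter on low values and 61 with the column number as a term. In the fit with all libraries, 1878 genes had an unadjusted p under 0.05.

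The interaction tested, gene by gene, whether DKO differed from Cebpa-KO as the libraries labelled Trib1-KO differed from WT. It called 2490 genes. For 1257 of them the difference between DKO and Cebpa-KO was the higher of the 2 differences, and for 1233 it was the lower. Genes picked for a rise in the libraries labelled Trib1-KO had a median of 0.98 with Cebpa and 0.02 without it, and genes picked for a fall had -0.58 and -0.02. Across 19810 genes the log2 fold changes with and without Cebpa, which share no library, had a correlation of 0.0284 (SE 0.0470 from leaving out libraries), and 0.0625 over the 4498 genes called with Cebpa. Of the 40 genes called between DKO and Cebpa-KO, 22 were also called with Cebpa intact, 6 up in both, 7 down in both and 9 up with and down without Cebpa, against 1.88, 2.63 and 2.82 for independent lists. By list, the female-biased genes (median -1.82), complement and coagulation (0.68), xenobiotic metabolism (0.92) and plasma carriers (0.50) passed in the interaction with either correlation, with adjusted p of at most 0.046 with an estimated correlation. Klkb1, Alb and Cyp2c29, for example, were 1.23 ± 0.10, 1.77 ± 0.21 and 3.85 ± 0.16. The share of interaction calls with a positive sign was 50.5% against 17.9% with the Mup-free scaling.

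**Figure D3:**
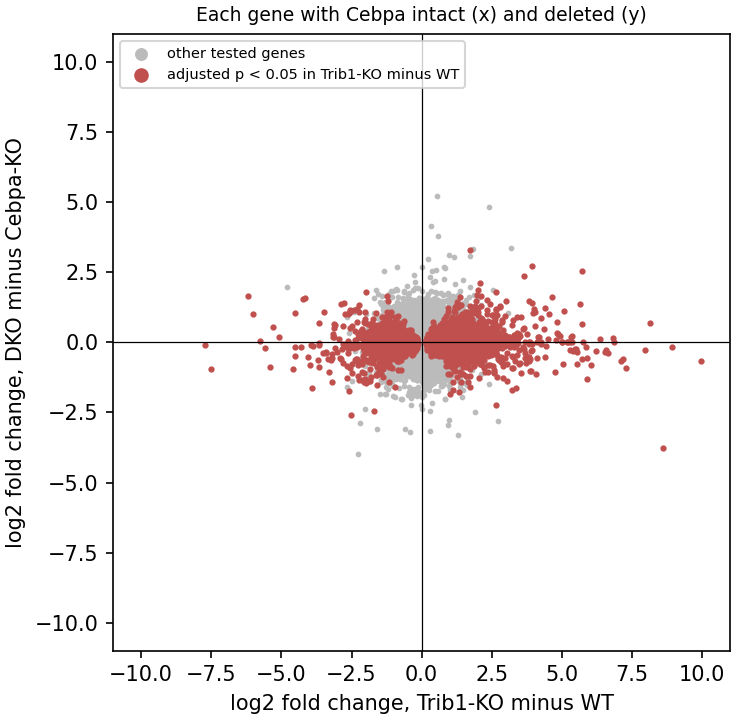
Each of 19810 genes by its log2 fold change between the libraries labelled Trib1-KO and WT (x axis) and between DKO and Cebpa-KO (y axis), with genes called in the first comparison in red. The red points spread along the x axis, with a correlation over them of 0.0625.

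DKO and the libraries labelled Trib1-KO differ by the floxed Cebpa gene. This comparison had the most calls, 2901 up and 3105 down, 904 and 1482 of them by at least 2-fold. The largest rises in all 6 libraries were Clec2h at 9.84 ± 0.30, Selenbp2 at 8.99 ± 0.33, Obp2a at 8.11 ± 0.40, Rian at 7.12 ± 0.26, Enho at 6.73 ± 0.31 and the axonemal dynein gene Dnaic1 at 6.68 ± 0.62. The largest falls were Mup15 at -14.76 ± 1.76, Mup18 at -13.85 ± 0.99, Mup17 at -12.13 ± 0.97, Mup19 at -11.25 ± 1.31 and Mup8 at -10.46 ± 0.66. Moxd1 was listed at 0 in all DKO libraries, and the Mup sum was -3.27 ± 0.24 (exact permutation p = 0.00216, the smallest possible). Complement and coagulation genes numbered 22 up and 2 down of 28 (22 and 2 adjusted over the list alone, camera adjusted p = 1.0e-12, and adjusted p = 0.26 with an estimated correlation). C8a stood at 2.76 ± 0.14. Xenobiotic metabolism numbered 16 up and 4 down of 24 (16 and 4 adjusted over the list alone, camera adjusted p = 9.3e-09, and adjusted p = 0.021 with an estimated correlation) and female-biased genes 0 up and 12 down of 20 (1 and 12 adjusted over the list alone, camera adjusted p = 1.3e-07, and adjusted p = 0.010 with an estimated correlation). Cyp2c29 stood at 4.57 ± 0.11 and Cyp17a1 at -6.17 ± 0.31. Plasma carriers numbered 12 up and 5 down of 18 (13 and 5 adjusted over the list alone, camera adjusted p = 6.3e-04, and adjusted p = 0.33 with an estimated correlation). Alb stood at 2.44 ± 0.15. Fatty acid and triglyceride synthesis numbered 2 up and 14 down of 22 (2 and 15 adjusted over the list alone, camera adjusted p = 9.2e-05, and adjusted p = 0.42 with an estimated correlation). Fasn stood at -2.10 ± 0.18. Lipid droplet genes numbered 4 up and 9 down of 19 (4 and 13 adjusted over the list alone, camera adjusted p = 0.0062, and adjusted p = 0.47 with an estimated correlation). Cidec stood at -5.09 ± 0.47.

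In the same comparison, extracellular matrix genes numbered 0 up and 12 down of 16 (0 and 15 adjusted over the list alone, camera adjusted p = 1.3e-05, and adjusted p = 0.33 with an estimated correlation), macrophage markers 0 up and 7 down of 12 (0 and 10 adjusted over the list alone, camera adjusted p = 0.0030, and adjusted p = 0.48 with an estimated correlation). Cell cycle genes numbered 1 up and 15 down of 25 (2 and 15 adjusted over the list alone, camera adjusted p = 0.0030, and adjusted p = 0.47 with an estimated correlation), immediate early genes 1 up and 8 down of 12 (2 and 8 adjusted over the list alone, camera adjusted p = 0.0034, and adjusted p = 0.48 with an estimated correlation), and interferon-stimulated genes 1 up and 8 down of 18 (2 and 8 adjusted over the list alone, camera adjusted p = 0.025, and adjusted p = 0.70 with an estimated correlation). Timp1, Cd68, Mki67, Atf3 and Gbp3 stood at -3.62, -1.18, -1.89, -5.16 and -1.74. Hepatic stellate cell markers numbered 0 up and 5 down of 12 (0 and 6 adjusted over the list alone, camera adjusted p = 0.029, and adjusted p = 0.48 with an estimated correlation), NRF2 genes 2 up and 9 down of 15 (5 and 9 adjusted over the list alone, camera adjusted p = 0.042, and adjusted p = 0.48 with an estimated correlation) and ribosomal proteins 0 up and 11 down of 26 (0 and 12 adjusted over the list alone, camera adjusted p = 0.0041, and adjusted p = 0.55 with an estimated correlation). Oxidative phosphorylation numbered 14 up and 0 down of 22 (17 and 0 adjusted over the list alone, camera adjusted p = 1.3e-05, and adjusted p = 0.48 with an estimated correlation), and its median of 0.21 turned to -0.08 with the Mup-free scaling. Vldlr stood at -5.57 ± 0.36, Insig2 at -3.19 ± 0.16 and Anxa2 at -2.71 ± 0.10, while Apob was 0.30 ± 0.07 (adjusted p = 0.0020). With the Mup-free scaling Apob no longer passed (0.02, adjusted p = 0.86, in a range from 4.9e-06 to 0.86 over 12 alternatives). Cebpa deletion had related effects with and without a floxed Trib1 gene, since 653 rises and 650 falls were shared with Cebpa-KO against WT, against 134 and 162 for independent lists, in comparisons that share no library. Over the 1946 genes called in Cebpa-KO the correlation across genes was 0.79, with 87.3% of the same sign, and over all 19810 genes it was 0.43 with 61.2%. Camera called 15 of 37 lists, 4 up and 11 down, and fry 24. The share of calls that rose was 48.3% against 18.7% with the Mup-free scaling.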

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

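The tests of swapped labels, of scaling, of leftover exons, of the share of hepatocytes, of the sex of the mice and of DNA beside Trib1 were chosen after the results were seen, as were the 3 patterns weighed, the fit without Cebpa-KO F3 and DKO H1 and the second condition on their labels. The rule for DNA of another strain elsewhere was made stricter after its value was seen, which changed that verdict from excluded to open. With group labels redrawn in 100 splits per comparison, the real labels included, 1 of 100, the real split, gave as many calls in each. No smaller share is possible with 100 splits, so chance was made unlikely for each count but not excluded. The margin was small for DKO against Cebpa-KO, where 14 other splits gave calls. The real count and the highest other were 4498 against 1964 for the libraries labelled Trib1-KO, 1946 against 471 for Cebpa-KO, 1206 against 277 for DKO, 40 against 30 for DKO against Cebpa-KO, 6006 against 2232 for DKO against the libraries labelled Trib1-KO and 2490 against 23 for the interaction.

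A library far from the other 5 of its group was found in 29 of 181 tests over 46 genes, where chance gives about 1 in 20 (9.05 tests). The value is the gap to the nearest library as a part of the group's range. Trib1 stood at 646 normalized counts in Cebpa-KO F3 (0.628), above the others, and at 286 in DKO H1 (0.632), below them. Cebpa in Cebpa-KO E2 was the lowest (0.6255). In WT B3, Mup19, Mup15 and Mup7 were lowest (0.785, 0.820 and 0.710), while Lrtm2 and Tff3 were highest (0.828 and 0.813). In WT A1, Mas1 was highest (0.781) and Cspg5 lowest (0.790).

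In the libraries labelled Trib1-KO, D2 was highest for Moxd1 (0.690), Ugt2b38 (0.901), Mas1 (0.794) and Serpina1e (0.690), and C2 for Rnf186 (0.708). A value of 1 marks genes listed at 0 in the other 5 libraries, which held for Clec2h and Adam32 in D1 and Dnaic1 in C1 of the libraries labelled Trib1-KO, Sult3a1 and Gldn in Cebpa-KO E1, and Sprr1a in DKO G1. In Cebpa-KO, E1 was highest for Moxd1 (0.790) and Cib3 (0.789), and E3 lowest for Meg3 (0.794) and Slc1a5 (0.729). In DKO, H3 was highest for Enho (0.732) and H1 for Cib3 (0.692), while H2 was lowest for Meg3 (0.842) and G1 for Cspg5 (0.646).

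The difference between DKO and Cebpa-KO departed from that between the libraries labelled Trib1-KO and WT, as tested by the interaction term, for 2490 genes. Among them, Cebpa itself stood at 1.17. Cebpa is floxed in both DKO and Cebpa-KO and was low in both (82.4 and 82.2 normalized counts). Its value thus repeats, with the sign turned, the -1.16 of the libraries labelled Trib1-KO against WT. Apob stood at 0.36, which passed under 9 of 11 alternatives and fell to 0.12 (limma adjusted p = 0.44) with scaling without Mup genes. The largest positive values were Selenbp2 7.61, Clec2h 6.56, Enho 5.87, Dnaic1 5.77, Obp2a 5.73 and Tff3 5.56. The largest negative values were Mup18 -12.38, Cyp2b9 -10.64, Sult3a1 -9.09, Gldn -8.24, Moxd1 -8.22 and Sprr1a -7.79. Of these, Sult3a1, Gldn and Moxd1 were listed at 0 in DKO, so that their values depend on the pseudocount. Those of Sprr1a, Clec2h, Dnaic1, Obp2a and Tff3 do too, since each had a group mean below the pseudocount of 1. Mup18 was listed at 0 in DKO H1 and H2, and Cyp2b9 in WT A2 and DKO G3. By gene list, the interaction held with an estimated correlation only for complement, plasma carriers, xenobiotic metabolism and female-biased genes. Medians above 0 with the preset correlation were 0.57 for cholesterol synthesis, 0.24 for bile acids, 0.35 for the urea cycle, 0.91 for acute phase proteins, 0.68 for complement, 0.50 for plasma carriers, 0.92 for xenobiotic metabolism, 1.08 for male-biased genes and 0.35 for periportal genes. Apolipoproteins stood at 0.20, which turned to -0.04 with scaling without Mup genes. Medians below 0, which held with an estimated correlation for female-biased genes alone, were -0.40 for fatty acid synthesis, -0.52 for lipid droplets, -0.64 for NRF2 genes, -1.82 for female-biased genes, -1.29 for the cell cycle, -0.96 for interferon-stimulated genes, -0.74 for matrix genes, -0.10 for ribosomal proteins, -0.67 for immediate early genes and -0.57 for macrophage markers.

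A pattern to weigh is Trib1, which was higher in the libraries labelled Trib1-KO than in WT. Swapped labels of these groups are argued against by the female-biased list, with 9 more members higher than lower in the libraries labelled Trib1-KO, a reading that rests on textbook knowledge that these genes are low in male liver. Scaling is argued against by the lowest log2 fold change of Trib1 under 3 other scalings, 1.76. Reads from the part of the gene left after the deletion stay open, since values per gene cannot place them in exons, and Trib1 stood at 1.13 between DKO and Cebpa-KO. A candidate explanation that stays open beside it is raised transcription of the deleted gene.

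Next is the fall of many complement, coagulation and plasma carrier genes with the rise of female-biased, macrophage and interferon genes in the libraries labelled Trib1-KO. Not all genes for secreted hepatocyte proteins fell, since the Mup sum rose by 1.91 ± 0.27. Acute phase proteins numbered 6 up and 5 down of 24. A lower share of hepatocytes alone would raise the markers of every other cell type alike. The macrophage score rose by 0.63 more than the endothelial score, and the cholangiocyte score was -0.56 ± 0.15. These values argue against a lower share as the only cause. They cannot decide on a lower share together with more macrophages, since the macrophage rise is part of the pattern. A larger share of reads from Mup genes is argued against by 17 complement and coagulation genes still called lower with Mup genes left out of the scaling. Female mice are argued against by a lowest value of 219 for 4 Y-linked genes in the 6 libraries. Trib1 deletion, which values per gene cannot show, may be the cause as a hypothesis, and a larger number of macrophages stays open.

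The last pattern is the calls between DKO and Cebpa-KO. DNA of another strain around the floxed Trib1 gene, acting on genes beside it, is argued against as the source of the calls by 39 of 39 called genes other than Trib1 that lie more than 20 Mb from it. The count first planned, over the windows of Trib1 and Cebpa, was 2 (1.60 expected from the genes tested, 1-sided Fisher p = 0.48). It decides nothing, since both called genes lie near Cebpa, which is floxed in both groups. Such DNA elsewhere stays open, with 4 pairs of called genes within 5 Mb, the same as the median of 10000 random draws (1-sided permutation p = 0.58). Exchanged labels of Cebpa-KO F3 and DKO H1 had been expected to put F3 above 0.5 and H1 below 0.5 on a scale from the Cebpa-KO mean (0) to the DKO mean (1), and they lay at 0.669 and 0.248. After that result was seen, a second condition was added, that both lie on the other side for the 24 genes that separate the other 10 libraries, and this held for 6 of them, while both lay on their own side for 6. With each library placed by genes picked without it, F3 (0.587) and H1 (0.343) lay on the other group's side. Every other library of the 2 groups lay on its own side, DKO H2 narrowly (0.502). Without F3 and H1, Trib1 was 1.59 between DKO and Cebpa-KO (limma adjusted p = 4.9e-07), though its values had drawn attention to both. The first condition went with an exchange and the second left it undecided. An exchange therefore stays open beside spread within the groups, and Trib1 deletion without Cebpa remains the open biological explanation.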

How the results depend on the processing

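The scalings, the column terms, the fits without WT B3, Cebpa-KO F3, DKO H2 and DKO H3 or without Cebpa-KO F3 and DKO H1, and the split of WT by column letter were chosen after the data were seen. Of 12544 combinations of a named gene, a comparison and an alternative, 12040 kept their direction and side of the threshold, 305 lost a call, 130 gained a call, 66 changed sign without a call either way and 3 reversed with a call. The counts of calls for the libraries labelled Trib1-KO and Cebpa-KO against WT, for DKO against the libraries labelled Trib1-KO and for the interaction stayed within 1.5 times their value under all alternatives run. That for DKO was 793 with only the 2 groups compared in the fit, where fewer libraries give the variance.

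The 40 calls between DKO and Cebpa-KO were 25 without the filter, 18 with only the 2 groups in the fit, 61 with the column number as a term and 79 without Cebpa-KO F3 and DKO H1, of which 35 were among the 40, and the cause was not tested. With a library left out they ranged from 18 to 63, at 23, 24, 26, 23, 26 and 63 without Cebpa-KO E1, E2, E3, F1, F2 and F3 and 18 without DKO G2. The other counts ranged with a library left out from 4084 to 4519 for the libraries labelled Trib1-KO, 1583 to 1866 for Cebpa-KO, 964 to 1149 for DKO, 5500 to 5759 for DKO against the libraries labelled Trib1-KO and 2258 to 2596 for the interaction.

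Values that reversed did so with scaling to library totals without Mup genes, which by construction raises other genes where Mup genes take a larger share. These were Apob in the libraries labelled Trib1-KO (0.033, adjusted p = 0.77, 7.6e-04 to 0.77 over alternatives), and Cop1, the ubiquitin ligase gene, in the libraries labelled Trib1-KO (0.24, adjusted p = 0.0080, 0.0080 to 1) and between DKO and those libraries (-0.28, adjusted p = 0.0021, 0.0021 to 1). The cause was not tested beyond the scaling itself.

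With an estimated correlation, camera called 2 lists for the libraries labelled Trib1-KO, 2 for Cebpa-KO, 1 for DKO, 0 for DKO against Cebpa-KO, 2 for DKO against the libraries labelled Trib1-KO and 4 for the interaction, since a larger correlation within lists widens the test. Fry called 27 lists for the libraries labelled Trib1-KO, 13 for Cebpa-KO, 11 for DKO and 21 for the interaction. It called 0 for DKO against Cebpa-KO and 24 for DKO against the libraries labelled Trib1-KO. Camera with the preset correlation called 21 for DKO against Cebpa-KO without Cebpa-KO F3 and DKO H1, and the cause was not tested. Acute phase proteins in DKO went from up (adjusted p = 0.27) to down (adjusted p = 0.0019) without WT B3, Cebpa-KO F3, DKO H2 and DKO H3. The 936 genes called both in the libraries labelled Trib1-KO and in Cebpa-KO were 540 with WT A1 to A3 for the first and B1 to B3 for the second, and 528 the other way round, where 3 WT libraries in place of 6 lower the number of calls.

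No paired analysis was possible because the labels pair no mice. Not run were alternatives that need counts (other count normalizations, count filters and DESeq2) and those that need the cohort of each column (a cohort term, each cohort alone, and WT split by cohort). Median-ratio scaling on top of the deposited values gave equal factors and changes nothing. Depth, at an estimated 18640900 to 34286900 reads per library, limits what can be called among genes with low values. The simulated 2-fold changes, of which 68% were recovered, were not placed in such genes and cannot show this limit.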

Other observations

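The imprinted genes and the column numbers were looked at after the calls were seen. Meg3 (chromosome 12, 109541001 to 109571726), Rian (109603940 to 109661716) and Mirg (109729764 to 109749460) lie side by side in an imprinted cluster and are noncoding. In Cebpa-KO they stood at 4.24 ± 0.22, 4.50 ± 0.26 and 2.99 ± 0.49 and in DKO at 3.60 ± 0.22, 3.87 ± 0.26 and 2.92 ± 0.49, all with an adjusted p of 4.3e-04 or less. In the libraries labelled Trib1-KO, Meg3 and Rian stood at -2.01 ± 0.22 and -3.25 ± 0.26, and Mirg at -0.71 ± 0.49 did not pass (adjusted p = 0.35). Dio3 (110279068 to 110281097), a paternally expressed gene of the same cluster, fell in the libraries labelled Trib1-KO (-1.53 ± 0.53, adjusted p = 0.038) and did not pass in Cebpa-KO (-0.18 ± 0.53) or DKO (-0.91 ± 0.53).

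The first component of the residuals, with 11.0% of their variance, followed the number in the column names. Of 8 libraries per number, 8 lay below 0 for number 1, 5 for number 2 and 1 for number 3. Residuals of libraries from different groups with the same number correlated at 0.0174 on average over 72 pairs, against -0.00863 for different numbers. What the numbers stand for is not given in the labels. If the columns follow the order of the sample titles, number 1 lies in the first cohort, number 3 in the second and number 2 in both. The component may then reflect the cohorts, which was not tested.

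The sex-linked genes matched the male mice of the labels. Ddx3y, Eif2s3y, Kdm5d and Uty, on the Y chromosome, had a lowest value of 207 normalized counts over the 24 libraries, and Xist, which is expressed from an inactive X chromosome, a highest of 22.4.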
